A study of Homo sapiens with 10 samples.

How the data were processed

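RNA was measured on 10 gene-level exon arrays in DLD-1 colorectal cancer cells, in 8 clones or cultures. Per the labels, cells grew in RPMI with serum, all but the wild type cells under puromycin. Total RNA was extracted with Trizol and depleted of ribosomal RNA, and biotin-labelled single-stranded cDNA was hybridised. The deposited values are 1 log2 value for each of 22011 probes, each a transcript cluster, on each array. The log2 base was read from the range of the values and is not stated in the labels. The authors' background correction, normalization and summary of probes are not given in the sources used here. Array medians were 7.34 to 7.41 but for clone 8 at 7.62. The values were taken as deposited with no further scaling, and scalings were tried as alternatives. The raw intensities were not used here. The titles of the 3 construct V2LHS_62675 samples give clone 12 and call them biological replicates, while their descriptions and the design text give repeats of clone 2, which was followed here. Array 1 of these correlated with arrays 2 and 3 at 0.988 each, and arrays 2 and 3 with each other at 0.995, so array 1 lay no closer to them than arrays of different clones lie to each other (0.986 to 0.994). Its highest correlation was 0.991, with clone 12 of construct V2LHS_62673, so the arrays do not settle which label is right.

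Of the probes, 14432 carry 1 gene symbol, 2408 several and 5171 none. The 14432 single-symbol probes cover 14233 genes, and of the 196 genes with more than 1 such probe the probe with the highest mean was used. Symbols were matched to a reference table of human genes (GRCh38) by gene identifier, which held 14404 of these probes. Probes with a mean under the 25th percentile of all probes, a log2 level of 5.96, were left out, which left 11198 genes. The only probe for LMNB1 is shared with PCIF1 by annotation and was tested beside them as 1 more feature, making 11199. Levels of genes on the Y chromosome and of XIST are not reported.

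The 3 arrays of clone 2 are repeats of 1 clone by the design text and were averaged, which gives 8 clone-level samples, 4 knockdown clones and 4 controls. Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The main fit had 6 residual degrees of freedom and a prior of 3.91. A fit of the 4 groups, with 4 residual degrees of freedom, gave the contrasts of construct V2LHS_62673, clone 2 and wild type cells with the empty vector clones, and of clone 2 with construct V2LHS_62673. These degrees of freedom and the prior are those with all clones. Without clone 8 the fit of the 4 groups had fewer. Its spread came from the 3 empty vector clones and from clones 9 and 12 alone. Clone 2 and wild type cells enter as 1 sample each. The p-values measure the spread between clones, and for these 2 they assume that of the other groups. LMNB1, LMNB2, LMNA and LBR were also tested with exact permutation tests of the 8 values.

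Before the data were examined, 27 gene lists with 1042 entries were fixed, of which 815 have a single-gene probe. They cover the nuclear lamina and envelope, nuclear pore, DNA replication and S phase, replication-dependent histones, G2/M and mitosis, condensin and cohesin, heterochromatin, DNA damage, p53 targets, senescence, interferon, unfolded protein and amino acid stress, colon differentiation, Wnt targets, epithelial junctions, mesenchymal, leukocyte and endothelial markers, hypoxia, cholesterol synthesis, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, immediate early genes, heat shock, NF-kB and microRNA processing. They were tested with limma's camera, with its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. The genes of each chromosome were tested the same way. The list tests in the comparisons other than the main one were not part of the design fixed beforehand. Members were also adjusted over each list alone.

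The genes named are the lamins, and in the main comparison the 10 largest changes each way among genes past the threshold whose groups do not overlap, filled with the smallest p where fewer pass. In each list they are up to 4 members with the smallest p. In the other comparisons they are the 5 largest changes each way past the threshold, or the 3 smallest p where none passes, and for both constructs the 5 largest shared changes each way. The comparisons, tests, lists and naming rule were fixed before the data were examined.

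The alternatives were quantile normalization, median centring, no filter or a filter at the 50th percentile, the mean of a gene's probes, a trended robust prior, array weights, clone as a random block, every array as a replicate, fewer controls or constructs, a running median over 51 neighbouring genes removed, the replicate number as a block, an estimated correlation, and leaving out each clone or array. Centring each array within the 2 runs of probe identifiers, and 3 combinations without clone 8, were added after seeing the data, as was the fit of the arrays of clone 2 and the empty vector clones alone. Chance sharing of controls was simulated with 100 draws of the spread.

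The tests were checked on simulated data with the real spread, in which 200 of 11198 genes were changed. In the main comparison with all clones, 35.8% of 1.5-fold, 70.1% of 2-fold and 98.5% of 4-fold changes were recovered, and 70.1%, 92.5% and 100% without clone 8. For construct V2LHS_62673 the shares were 5.97%, 32.8% and 90.9% with all clones and 56.7%, 89.6% and 100% without clone 8. For clone 2 they were 0%, 1.49% and 45.5% with all clones and 25.4%, 80.6% and 93.9% without clone 8, and for wild type cells 0%, 2.99% and 54.5%, and 40.3%, 89.6% and 97.0%. With no change put in, no gene was called. With the changes put in, 0 to 8 unchanged features were called in each comparison. The simulation gave every sample the same spread for a gene. Clone 2 and wild type cells thus had by construction the spread that their tests assume, and the excess of clone 8 was spread over all samples. The check therefore cannot show how many of the real calls are false, nor the exact recovery with clone 8 included. A shift of 0.2 put into the replication list was found by camera with an adjusted p of 7.06e-05, and adjusted p = 0.0313 with an estimated correlation. This list check did not carry over the real correlation between genes. In the main comparison that correlation was estimated at 0.26 for the replication list. Among the lists that passed there, it ran from 0.0094 for hypoxia and glycolysis to 0.73 for leukocyte markers. The list check therefore cannot show how the list tests behave where members are correlated. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.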

Results

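RNA levels were measured on 10 gene-level exon arrays in DLD-1, a human colorectal cancer cell line. Cells carried short hairpin RNA (shRNA) against LMNB1, which encodes lamin B1, a filament protein of the nuclear lamina. Construct V2LHS_62673 gave 3 single cell clones, numbers 8, 9 and 12, with 1 array each. Construct V2LHS_62675 gave 1 clone, number 2 by the sample descriptions, with 3 arrays. The negative controls were 3 clones with an empty vector, 1 array each, and wild type cells with 1 array. The array of clone 8 stood apart from the other 9 arrays. Its correlation with them over 22011 probes was 0.915 to 0.926, while the others correlated at 0.986 to 0.995 with each other. The median log2 level was 7.62 in clone 8 and 7.34 to 7.41 in the others, and the 25th percentile was 6.32 in clone 8 and at most 5.96 elsewhere. For this reason the comparisons were also made without clone 8, which was one of the planned omissions of single clones. Many of those values, though not those of each named gene, are given beside the ones from all clones. The choice to report them at length was made after seeing the data. The number of arrays limits the precision of every comparison.

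The first question was whether the hairpins lowered their target and what happened to the other lamins. The probe for LMNB1 was lower in all 4 knockdown clones than in all 4 controls, at 7.65 ± 0.14 against 9.11 ± 0.30 log2 units (mean ± SD, n = 4 each). The difference was -1.46 (SE 0.17, 95% interval -1.83 to -1.09), which is 2.75-fold and leaves 36.3% of the control signal. An exact permutation test of the 4 against 4 values, two-sided, gave p = 0.0286, the smallest that its 70 regroupings allow. The same difference had an adjusted p of 0.0603 in limma over all features, which misses the threshold of 0.05, and it missed it without clone 8 as well. The 2 constructs gave like levels, 7.65 ± 0.18 in the 3 clones of construct V2LHS_62673 and 7.67 in clone 2, whose 3 arrays had an SD of 0.09. Against the empty vector clones, at 8.98 ± 0.17, the differences were -1.33 (SE 0.17) and -1.31 (SE 0.24), and they differed from each other by 0.02 (95% interval -0.53 to 0.58). Their adjusted p in limma was 0.214 and 0.863 with all clones, and 9.14e-04 and 0.00372 without clone 8, which pass. Wild type cells had the highest level, 9.52, which was 0.54 (SE 0.24) above the empty vector clones. The array annotation assigns this probe to LMNB1 and to PCIF1, which encodes an RNA cap methyltransferase, so its signal is not specific to 1 gene. LMNB2, the other B-type lamin, was 9.83 ± 0.22 in knockdown and 9.59 ± 0.11 in controls (n = 4 each, exact permutation p = 0.0571). LMNA, the source of lamins A and C, was 9.92 ± 0.22 in knockdown and 10.13 ± 0.13 in controls (n = 4 each, exact permutation p = 0.143). The lamin B receptor gene LBR differed by 0.15 (SE 0.13, n = 4 each, exact permutation p = 0.257). None of these 3 genes passed the test.

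**Figure D1:**
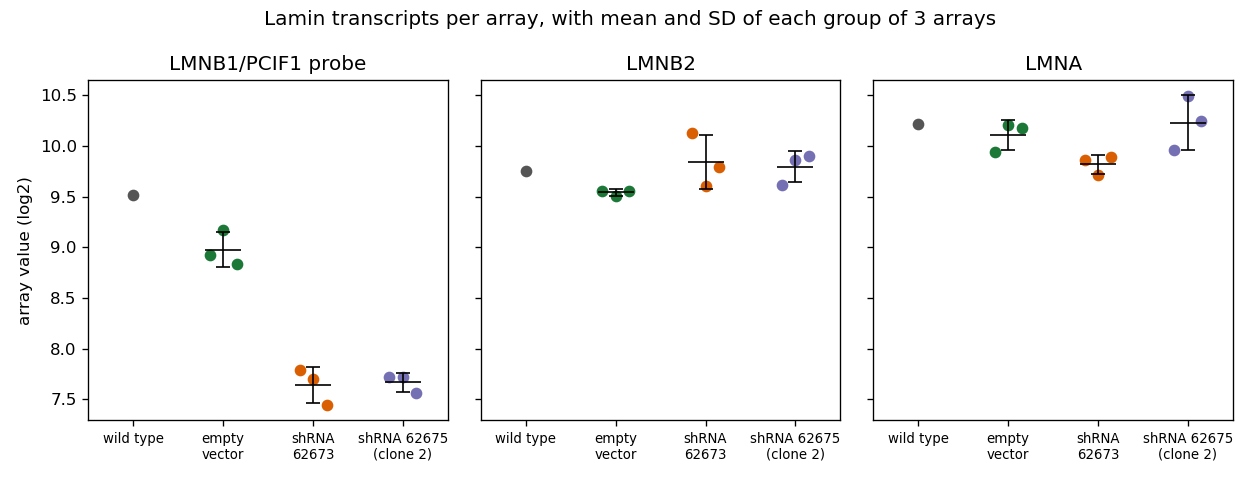
Array value (log2) of the LMNB1/PCIF1 probe, LMNB2 and LMNA in each group, with each point 1 array and the lines the mean and SD of each group of 3 arrays. The knockdown arrays lie between 7.45 and 7.79 for the LMNB1/PCIF1 probe and the controls between 8.84 and 9.52.

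The main comparison asked which other genes differ between the 4 knockdown clones and the 4 negative controls. The genes with the smallest p among those whose groups did not overlap included ZNF738, a zinc finger gene, at 8.43 ± 0.19 in knockdown and 7.27 ± 0.29 in controls (mean ± SD, n = 4 each), a log2 difference of 1.16 (SE 0.17). On the lower side stood RAB25, a small GTPase of epithelial membrane recycling, at 9.75 ± 0.20 against 10.48 ± 0.13, and CD44, the hyaluronan receptor, at 7.77 ± 0.30 against 8.55 ± 0.09. None of the 11198 genes passed in limma, where ZNF738 had an adjusted p of 0.258 and every other gene named in this paragraph 0.761, while 255 genes had an unadjusted p under 0.05. Other genes on the higher side were SF3A1 of the U2 splicing particle (0.61, SE 0.15), the Ras-like GTPase DIRAS2 (0.71, SE 0.19), TPRG1 (0.60, SE 0.16) and the zinc finger gene ZNF875 (0.59, SE 0.17). The same side held the ribosome assembly GTPase BMS1 (0.46, SE 0.13), the bitter taste receptor TAS2R31 (0.63, SE 0.19), the co-chaperone DNAJA1 (0.54, SE 0.17), YLPM1 (0.40, SE 0.13) and the brush border scaffold ANKS4B (0.47, SE 0.16). Zinc finger and taste receptor genes have near-identical copies that can share probe signal. On the lower side, RAB25 differed by -0.73 (SE 0.14) and CD44 by -0.78 (SE 0.16). They were joined by the ribosome assembly factor RPF2 (-0.66, SE 0.14), the sugar transporter SLC50A1 (-0.61, SE 0.14), TMEM141 (-0.82, SE 0.21), the retinol saturase RETSAT (-0.51, SE 0.13) and the RNA-binding protein KHDRBS3 (-0.74, SE 0.19). The remaining 3 were NAPRT of NAD synthesis (-0.56, SE 0.15), the orphan receptor GPR160 (-0.54, SE 0.14) and the peptidase APEH (-0.46, SE 0.13). Over all genes, 178 lay higher and 172 lower in every knockdown clone than in any control, 3.13% of genes, where chance gives 2.86%. Without clone 8 the count past the threshold was again 0 in limma, with 723 genes at an unadjusted p under 0.05. Array quality weights gave 6 genes and the empty vector clones alone as controls gave 2, LRRN1 and PLA2G2A, named after their values were seen. The p-values measure the spread between clones.

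With clone 8 left out and only the empty vector clones as controls, a combination chosen after seeing the data, 18 genes passed in limma, 5 up and 13 down. ZNF738 rose by 1.24, MGST1, a glutathione transferase of the endoplasmic reticulum, by 0.92, SMC3, a cohesin subunit, by 0.76, and NUFIP1 by 0.71. The secreted phospholipase PLA2G2A (-2.14), LRRN1 (-1.85) and TMEM47 (-1.69) fell. So did ID1 (-0.79) and ID3 (-0.78), inhibitors of basic helix-loop-helix transcription factors, the mitochondrial isocitrate dehydrogenase IDH2 (-0.83), RAB25 (-0.69) and KHDRBS3 (-0.95). Wild type cells, which carry no hairpin, also passed in the same direction against the same empty vector clones for most of these genes. Among them were NUFIP1 (1.09), MGST1 (0.86), SMC3 (0.76), LRRN1 (-1.96), PLA2G2A (-1.76), ID1 (-0.89), IDH2 (-0.64) and KHDRBS3 (-0.75). ZNF738 (0.48), TMEM47 (-0.81), ID3 (-0.51) and RAB25 (-0.21) did not pass in wild type cells. The genes were picked against the same 3 empty vector arrays, which by itself favours a shared direction, so no count of shared genes is given. These genes were named after their values were seen.

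The next question was whether groups of genes, fixed before the data were examined, moved together in the same comparison. Of 27 lists, 6 passed limma's camera test with its preset correlation, 4 lower and 2 higher in knockdown. None of them passed with a correlation estimated from the data. Nuclear pore genes fell by 0.19 on average, with 19 of 22 measured members lower, among them NUP54 (-0.51, SE 0.34), NUP155 (-0.50) and NUP210 (-0.23), while NUP93 stood at 0.18. The list had an adjusted p of 0.00952, and adjusted p = 0.952 with an estimated correlation. Its mean was -0.73 in clone 8 and between 0.04 and 0.10 in the other 3 knockdown clones, against the empty vector mean. Genes of the unfolded protein and amino acid stress response fell by 0.14, 25 of 37 lower, including PHGDH (-0.56, SE 0.25) and SHMT2 (-0.50, SE 0.20) of serine and glycine metabolism, DDIT3 (-0.47) and DNAJB9 (-0.29). That list had an adjusted p of 0.00952, and adjusted p = 0.952 with an estimated correlation. Its mean was -0.23 without wild type cells, and -0.08, -0.09 and -0.08 without clone 12, empty vector clone 2 or empty vector clone 3, none of which passed. Hypoxia and glycolysis genes fell by 0.14, 22 of 29 lower, including NDRG1 (-0.68, SE 0.29), PDK1 (-0.67), the carbonic anhydrase CA12 (-0.55, SE 0.22) and KDM3A (-0.34). Here the adjusted p was 0.00952, and adjusted p = 0.444 with an estimated correlation. Cholesterol and fatty acid synthesis genes fell by 0.15, 19 of 26 lower, including ELOVL6 (-0.86), INSIG1 (-0.55), ACSS2 (-0.44, SE 0.16) and DHCR7 (-0.40), with an adjusted p of 0.0427, and adjusted p = 0.952 with an estimated correlation. That mean was -0.26 without wild type cells, which stood at -0.45 against the empty vector mean. Mesenchymal and extracellular matrix genes rose by 0.14, 21 of 23 higher, among them the YAP targets CCN1 (0.54, SE 0.23) and CCN2 (0.49, SE 0.17). Leukocyte markers rose by 0.14, 16 of 17 higher, among them CD53 (0.24) and CD68 (0.23). Both lists had an adjusted p of 0.0315, and adjusted p = 0.952 with an estimated correlation. Without clone 8 the means of these 2 lists were 0.06 and 0.01 and neither passed, and the nuclear pore mean was 0.01. No member of any of the 6 lists passed by itself, adjusted over the list alone or over all genes.

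**Figure D2:**
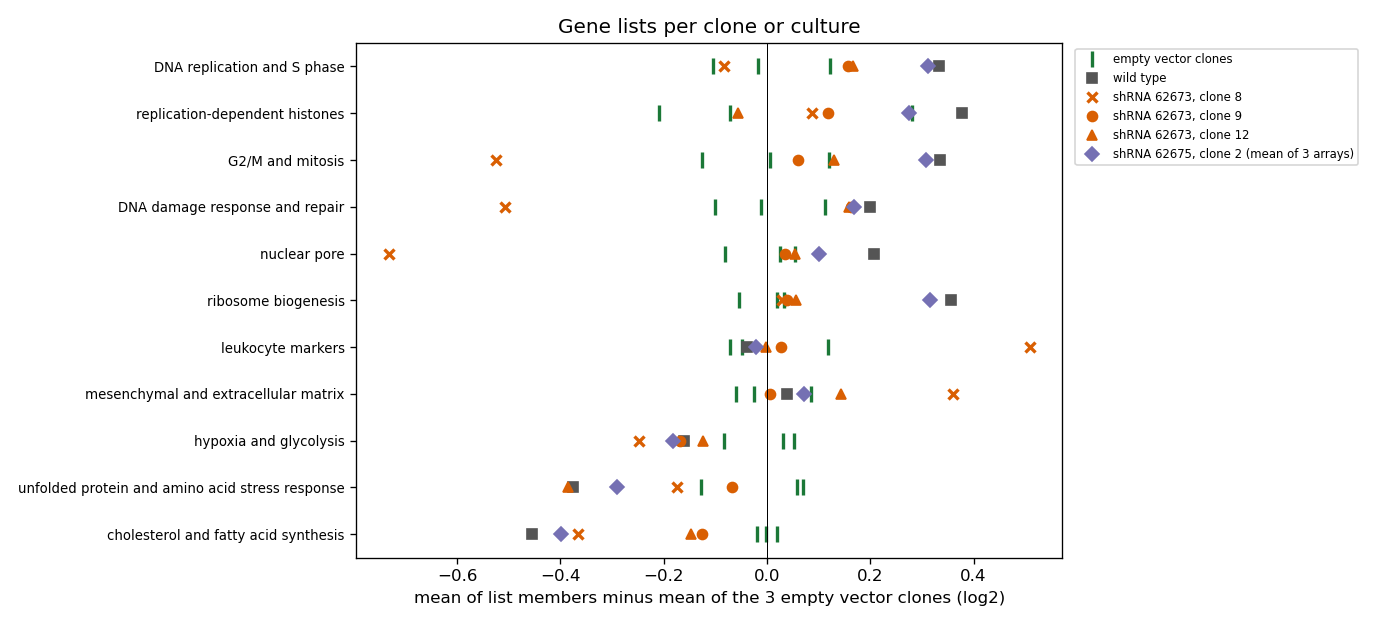
Mean log2 difference of the members of 11 of the fixed gene lists from the mean of the 3 empty vector clones, with 1 mark for each clone or culture and the mean of 3 arrays for clone 2. Clone 8 lies far from the other knockdown clones for nuclear pore genes (-0.73 against 0.04 to 0.10) and DNA damage genes (-0.51 against 0.16 to 0.17).

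Without clone 8 a partly different set of 5 lists passed camera, 3 higher and 2 lower, and 2 of them were among the 6 from all clones. Genes of DNA replication and S phase, the phase in which chromosomes are copied, rose by 0.13, with 45 of 53 higher (adjusted p = 1.03e-04). Among them were UHRF1 (0.26) and GINS4 (0.20), while POLE2 stood at -0.18. DNA damage response and repair genes rose by 0.11, 30 of 36 higher (adjusted p = 6.12e-04), and G2/M and mitosis genes by 0.08, 34 of 45 higher (adjusted p = 0.0324), with BIRC5 at 0.31. Hypoxia and glycolysis genes fell by 0.12, 23 of 29 lower (adjusted p = 0.00756), and the unfolded protein and amino acid stress response fell by 0.15, 29 of 37 lower (adjusted p = 0.00812). Each of the 5 had adjusted p = 0.894 with an estimated correlation. Over all alternatives the adjusted p ranged from 4.81e-11 to 0.994 for replication, 4.00e-06 to 0.968 for DNA damage, 2.78e-06 to 0.974 for G2/M, 0.00107 to 0.894 for hypoxia and 1.13e-05 to 0.952 for the stress response. Without clone 8 and wild type cells the means were 0.21 for replication, 0.16 for DNA damage, 0.17 for G2/M, -0.16 for hypoxia and -0.25 for the stress response. With all clones the replication list stood at 0.05 (33 of 53 higher, adjusted p = 0.231) and at 0.14 without wild type cells, the DNA damage list at -0.05 (0.643) and the G2/M list at -0.09 (0.231).

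The other lists did not pass camera in this comparison with all clones. The nuclear lamina and envelope list had a mean of 0.01 (adjusted p = 0.888), with 12 of 19 members higher, among them TMEM43 at 0.18. Replication-dependent histones had a mean of 0.01 over 34 genes and a test direction that was down, with H4C5 at 0.54 and H4C8 at 0.46 against H2AC21 at -0.61. Condensin, cohesin and chromosome structure genes had a mean of -0.03 (adjusted p = 0.636), with SMC3 at 0.47 and the topoisomerase TOP2B at -0.33. Heterochromatin and chromatin repression genes stood at -0.04 (0.636), where the Polycomb genes BMI1 (-0.42, SE 0.12) and EED (0.30) lay on opposite sides. BMI1 passed adjusted over the list alone when clone 8 was left out (0.0396) and not with all clones. The list of Wnt targets and crypt stem cells had a mean of -0.08 (0.366) and a median of 0.02, and its member CD44 passed when adjusted over the list alone (0.0149). Epithelial junctions and keratins had a mean of -0.10 (0.0557), and RAB25 passed adjusted over the list alone (0.0125). Neither gene passed over all genes tested. The mean was -0.04 for colon epithelium differentiation (0.888), though its median was 0.10, with MUC13 at -0.81, AGR2 at -0.71 and CDH17 at -0.65. Senescence and secretory factors had a mean of -0.01, a median of 0.11 and a test direction that was up (0.888), with EREG at -0.60. Means were -0.02 for p53 target genes with a median of 0.01, -0.08 for the interferon response (0.126), -0.09 for microRNA and shRNA processing (0.126) and 0.17 for endothelial markers (0.104, all 7 members higher). Without clone 8 these means were, in the same order, 0.03, -0.03, 0.0013 and 0.01, the last with 4 of 7 members higher. Ribosome biogenesis stood at 0.02, cytosolic ribosomal proteins at -0.05 with a median of 0.01, and oxidative phosphorylation at -0.06 (0.359). Immediate early genes stood at -0.02 (0.643), NF-kB targets at -0.01 with a median of 0.04 (0.814), and heat shock and protein folding at 0.06 with a median of -0.01 (0.481). Without clone 8 the means were 0.02 for the lamina, 0.02 for histones, 0.09 for condensin and cohesin and 0.01 for heterochromatin. They were -0.07 for Wnt targets, -0.07 for junctions, -0.11 for colon differentiation and -0.09 for senescence. Ribosome biogenesis then stood at 0.05, ribosomal proteins at 0.0047 and oxidative phosphorylation at -0.06. Immediate early genes stood at -0.09, NF-kB at -0.08 and heat shock at 0.09, and none of these lists passed camera.

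The clones of construct V2LHS_62673 were compared with the empty vector clones, which passed through the same selection and cloning. With clones 9 and 12 alone, LRRN1, a leucine-rich repeat membrane protein, fell by 1.85 (adjusted p = 3.58e-04), and PLA2G2A fell by 1.97 (SE 0.18, adjusted p = 0.0013). CHI3L1, a secreted chitinase-like glycoprotein (-1.71), the transporter SLC16A4 (-1.84) and TMEM47 (-1.57) fell as well. ZNF738 rose by 1.23 (SE 0.14, adjusted p = 0.00666), the chromatin organizer SATB1 by 1.11 (SE 0.19, adjusted p = 0.0267), the caveolar protein CAV1 by 1.00, MGST1 by 0.99 and the adaptor DOK3 by 0.93. Over the alternatives the adjusted p ranged from 3.51e-06 to 0.955 for LRRN1, 2.81e-05 to 0.956 for PLA2G2A, 7.96e-04 to 0.956 for ZNF738 and 0.00291 to 0.956 for SATB1. In all, 110 genes passed in limma without clone 8, 34 up and 76 down, with 1783 at an unadjusted p under 0.05. With all 3 clones 0 genes passed in limma, 358 had an unadjusted p under 0.05, and the smallest p belonged to LRRN1 (-1.81, SE 0.17, adjusted p = 0.113), PLA2G2A (-1.92, SE 0.22, 0.214) and the actin bundler FSCN1 (-1.38, SE 0.17, 0.214) on the lower side, and ZNF738 (1.28, SE 0.18), NUFIP1 (0.75) and MPP1 (0.74) on the higher side. Among the lists, 8 passed camera with all 3 clones, 2 higher and 6 lower, and 11 passed without clone 8, 4 higher and 7 lower. None passed with an estimated correlation, where the lowest adjusted p was 0.31 with all clones and 0.724 without clone 8. Without clone 8, replication genes rose by 0.16, 43 of 53 higher, with 7 members past adjusted over the list alone and none over all genes. DNA damage genes rose by 0.16, 31 of 36 higher. Cholesterol and fatty acid synthesis genes fell by 0.14, 16 of 26 lower, with 7 members past adjusted over the list alone and 3 over all genes, INSIG1 (-0.62), ACSS2 (-0.57) and TM7SF2 (-0.53), chosen for naming after their values were seen. Colon differentiation genes fell by 0.17, with 6 members lower and 1 higher adjusted over the list alone and 1 lower over all genes, the goblet cell peptide TFF3 (-1.11), also named after its value was seen.

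Clone 2 of construct V2LHS_62675 was compared with the same empty vector clones, and as 1 clone it is assumed to vary like the others. With the spread estimated without clone 8, the chloride channel CFTR fell by 2.10 (SE 0.13, adjusted p = 9.28e-05), and the sulfotransferase SULT1C2 fell by 2.71 (SE 0.29, adjusted p = 0.00191). PLA2G2A (-2.48), TMEM47 (-1.94) and the protein kinase PRKD3 (-1.93) fell as well. The cystatin CST7 rose by 1.501 (SE 0.18, adjusted p = 0.00418), EFHD1 by 1.47, PHLDB2 by 1.41, ZNF493 by 1.32 and the troponin gene TNNC1 by 1.30. Over the alternatives the adjusted p ranged from 2.84e-06 to 1.00 for CFTR, 3.39e-04 to 1 for SULT1C2 and 8.13e-04 to 1 for CST7. In all, 418 genes passed in limma, 172 up and 246 down, with 2033 at an unadjusted p under 0.05. With clone 8 in the spread 0 genes passed in limma and 295 had an unadjusted p under 0.05. The smallest p then belonged to CFTR (-2.10, SE 0.23, adjusted p = 0.228), INSIG1 (-1.73, SE 0.20, 0.228) and PLA2G2A (-2.48, SE 0.31, 0.258), and to CST7 (1.501), the phosphatase PTPRR (1.25) and TPRG1 (1.05). Replication genes rose by 0.31, 50 of 53 higher, with an adjusted p of 5.16e-12 in camera and adjusted p = 0.143 with an estimated correlation. Without clone 8, 7 of them passed over all genes and 21 adjusted over the list alone, among them GINS3 (0.83) and MCM2 (0.59) of the replicative helicase, named after their values were seen. G2/M genes rose by 0.31, 43 of 45 higher, with an adjusted p of 7.01e-09 and adjusted p = 0.262 with an estimated correlation. Of these, 7 passed over all genes and 15 adjusted over the list alone without clone 8, such as BIRC5 (0.79) and PLK1 (0.67), likewise named afterwards. Cholesterol and fatty acid synthesis genes fell by 0.40, 23 of 26 lower, and ribosome biogenesis genes rose by 0.32, 24 of 27 higher. These 2 lists passed also with an estimated correlation over all clones (adjusted p = 0.0325 each), but not without clone 8, where the lowest adjusted p over the 27 lists was 0.128. Without clone 8, 8 cholesterol members were lower over all genes and 13 adjusted over the list alone. In all 11 lists passed camera with all clones, 7 higher and 4 lower, and 10 without clone 8.

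Wild type cells were compared with the empty vector clones, which asks what vector, puromycin and cloning go with by themselves. The wild type culture is 1 array, assumed to vary like the clones. Here rose and fell mean higher and lower in wild type cells than in the empty vector clones. They do not say which of these changed. With the spread estimated without clone 8, LRRN1 was again lower, at -1.96 (SE 0.17, adjusted p = 0.00104), with the mitochondrial ribosome gene MRPS17 (-2.53, SE 0.28, adjusted p = 0.00501), the stress-induced mTORC1 inhibitor DDIT4 (-2.45, SE 0.43), SLC16A4 (-2.36) and SULT1C2 (-2.13). KBTBD8 rose by 1.58 (SE 0.18, adjusted p = 0.00501), the taste receptor TAS2R50 by 1.48, TNNC1 by 1.24, the bile acid transporter subunit SLC51B by 1.19 and the ribosomal RNA processing factor RRP36 by 1.13. Over the alternatives the adjusted p ranged up to 1 for these 3 genes, from 9.09e-05 for LRRN1, 2.25e-04 for MRPS17 and 0.00106 for KBTBD8. In all, 400 genes passed in limma, 188 up and 212 down, with 2207 at an unadjusted p under 0.05. With clone 8 in the spread 0 passed in limma and 290 had an unadjusted p under 0.05. Those with the smallest p were LRRN1 and INSIG1 (-1.55), each with an adjusted p of 0.481, TM7SF2 (-1.20), NUFIP1 (1.09), the kallikrein KLK10 (0.98) and EMC8 (0.79). Of the lists, 14 passed camera both with all clones and without clone 8, 8 higher and 6 lower. Replication genes rose by 0.33, 50 of 53 higher, with adjusted p = 0.159 with an estimated correlation. Without clone 8, 6 of them passed over all genes and 22 adjusted over the list alone. G2/M genes rose by 0.34, 43 of 45 higher, and replication-dependent histones by 0.38, 31 of 34 higher, with adjusted p = 0.239 and adjusted p = 0.281 with an estimated correlation. Stress response genes fell by 0.37, 31 of 37 lower, with adjusted p = 0.239 with an estimated correlation. Cholesterol and fatty acid synthesis genes fell by 0.45, 24 of 26 lower, and ribosome biogenesis genes rose by 0.36, 26 of 27 higher. These 2 passed with an estimated correlation over all clones (adjusted p = 0.019 each), and none passed so without clone 8, where the lowest adjusted p was 0.111.

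The last gene comparison tested whether the effects of the 2 constructs differ, clone 2 minus the construct V2LHS_62673 clones. Without clone 8, CHI3L1 was higher in clone 2 by 2.23 (SE 0.18, adjusted p = 4.25e-04), FSCN1 by 1.88, PTPRR by 1.61, the goblet cell gene SPINK4 by 1.39 and PHLDB2 by 1.36. SATB1 was lower in clone 2, at -2.58 (adjusted p = 0.00117), with CFTR at -2.18 (adjusted p = 1.14e-04), the matrix protein NPNT at -2.08, the netrin receptor NEO1 at -1.85 and LHFPL6 at -1.77. Over the alternatives the adjusted p ranged up to 0.9748 for these 3 genes, from 2.42e-05 for CHI3L1, 7.72e-05 for SATB1 and 2.68e-06 for CFTR. In all, 241 genes passed in limma, 104 higher and 137 lower in clone 2, with 1698 at an unadjusted p under 0.05. With clone 8 included 0 passed in limma and 249 had an unadjusted p under 0.05, led by CFTR (-2.28, adjusted p = 0.175), SATB1 (-2.47), CADPS (-1.28), PTPRR (1.66), FSCN1 (1.87) and CHI3L1 (2.05). Lists passed camera in 10 cases with all clones and in 7 without clone 8, none with an estimated correlation, where the lowest adjusted p was 0.154 and 0.281.

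Genes past the threshold against the empty vector clones under both constructs were counted without clone 8. There were 9 up in both and 29 down in both. Both comparisons take the same empty vector arrays, which by itself raises such counts, by an amount not computed. The genes up in both with the largest mean difference were ZNF738, CST7, MGST1, TPRG1 and DOK3, and those down in both were PLA2G2A, SULT1C2, LRRN1, TMEM47 and LURAP1L. SATB1 and CHAMP1 passed in opposite directions, SATB1 at 1.11 in construct V2LHS_62673 and -1.46 in clone 2 and CHAMP1, a chromosome alignment protein, at 0.54 and -0.63, both named after their values were seen. Across genes, the effects of the 2 constructs correlated at r = 0.435 without clone 8. Simulated effects that share only the empty vector arrays correlated at 0.316, and genes are not independent replicates. With all clones the correlation was 0.337 and the simulated one 0.353. That simulation took its spread with clone 8 included, which raised the simulated covariance to 0.0394 from 0.00626 without clone 8. The empty vector arrays are the same in both, so it cannot show what sharing them gives. The effects of clone 2 and of wild type cells correlated at 0.715, against 0.254 simulated, and shared 61 genes up and 106 down, again with the same empty vector arrays in both. Construct V2LHS_62673 and wild type cells correlated at 0.462 without clone 8, against 0.319 simulated, and at 0.233 with all clones, where the simulation has the same limit. Of the 5 genes named as down under both constructs, LRRN1 (-1.96), SULT1C2 (-2.13), PLA2G2A (-1.76) and LURAP1L also passed as lower in wild type cells, while TMEM47 (-0.81) did not pass. Of the 5 named as up, MGST1 (0.86) passed as higher.

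Because single cell clones can differ in chromosome copy number, the genes of each of 23 chromosomes were tested as a set. With all clones, 7 chromosomes passed camera in the main comparison. Chromosome 4 had a median difference of -0.08 and chromosome 19 one of 0.13, each with an adjusted p of 3.32e-04. The others were chromosomes 2, 3 and 5 on the lower side and 16 and 22 on the higher side. None passed with an estimated correlation, where their adjusted p was 0.445 on the lower side and 0.765 on the higher side. For 4 of them the shift lay mainly in clone 8, whose median against the empty vector mean was 0.50 for chromosome 19, 0.43 each for chromosomes 16 and 22 and -0.20 for chromosome 4. Chromosome 2 stood at 0.02 in clone 8 and -0.05 in clone 12, chromosome 3 at -0.05 in both, and chromosome 5 at -0.06 and -0.02. Without clone 8, 11 chromosomes passed, of which 2, 3 and 4 were among the 7. Leaving out wild type cells, empty vector clone 2 or clone 12 gave 2 chromosomes each, and leaving out empty vector clone 3 gave 11. On several arrays the values also shifted at 1 place in the order of the probe identifiers, between a run of 9061 probes and a run of 12950. Chromosome 8 has 268 probes in the first run and 262 in the second, and 7 of the 10 arrays differed between these interleaved runs (permutation test, adjusted over 10 arrays). The largest such step among the 9 arrays other than clone 8 was 0.08, first run minus second, in empty vector clone 2. Each array was then centred within each run, an alternative chosen after seeing the data. With this 0 chromosomes passed in limma's camera, with clone 8 or without it, so no chromosome is reported as changed between knockdown and controls. That comparison pools the clones, and a shift in a single clone was not tested. Chromosome 13 in clone 9 stood at 0.11 against the empty vector mean, the largest chromosome median outside clone 8. Chromosomes 12 and 14 of clone 9 stood at 0.0058 and 0.03. These values were picked after they were seen.

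**Figure D3:**
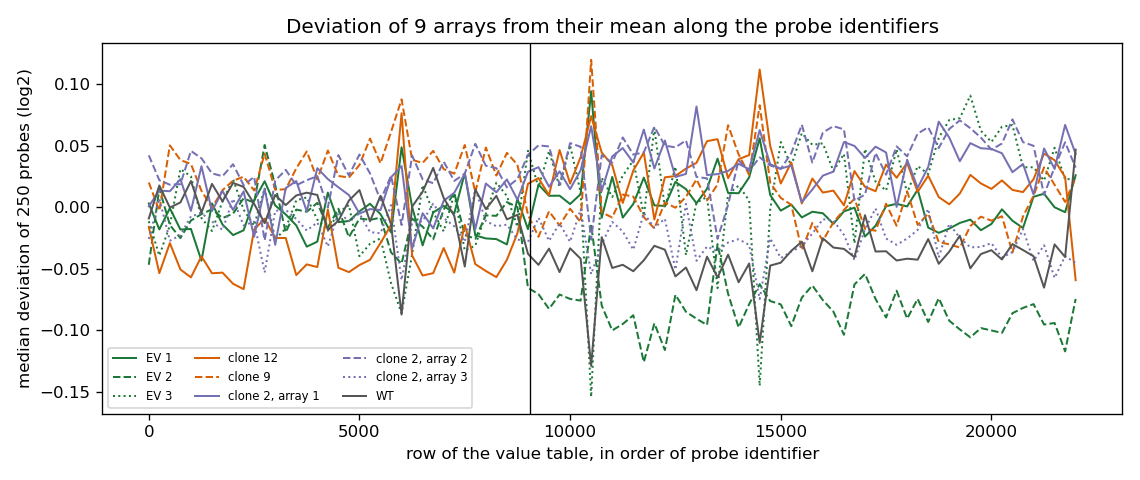
Median deviation (log2) of the 9 arrays other than clone 8 from their mean, along the rows of the value table in order of probe identifier, with 1 line for each array and a vertical line where the second run of 12950 probes begins. Several arrays step there. The median goes down from -0.01 to -0.08 in empty vector clone 2 and up from -0.04 to 0.03 in clone 12.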

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

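Of the tests in this part, those of the signal range, single markers and LMNB1 loss in clone 8, of probe sets and copy number for the step, and of array effects and LMNB1 loss for wild type cells and clone 2 were chosen after the result was seen, as were the splits of the gene counts. In groups of 4, a sample was singled out when its gap to the nearest other sample took up nearly the whole range. Of 102 such tests 13 singled out a sample and 8 of these were clone 8, while chance gives about 1 in 20, or 5.1.

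The array of clone 8 stood apart from the other knockdown clones in the SD over probes, 1.92 against 2.08 to 2.11 (2.077 to 2.105), and in 6 list means against the empty vector clones. Nuclear pore genes stood at -0.73 (others 0.04 to 0.10), condensin and cohesin at -0.32 (0.10 to 0.17), DNA damage at -0.51 (0.16 to 0.17) and microRNA processing at -0.33 (at most 0.05). Leukocyte markers stood at 0.51 (-0.02 to 0.03) and endothelial markers at 0.62 (-0.02 to 0.04). ANKS4B in clone 8 was 6.63 (6.08 to 6.15).

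For clone 8, a narrower signal range is argued against as the whole cause, since after quantile normalization its highest correlation with another array was 0.927, while the lowest among the others was 0.986. RNA of leukocytes, endothelial or mesenchymal cells was not shown but stays open. Their lists lay at percentiles 76.0, 92.6 and 84.5 of 10000 lists of the same size and level. None reached the percentile fixed beforehand, but only 17 of 30 leukocyte and 7 of 16 endothelial markers were measured. VIM, abundant in all 3 types, stood at 5.44 (highest other array 5.60). Other markers rose over the other arrays, PTPRC by 0.32, CD53 by 0.60, LCP1 by 0.43, PECAM1 by 0.74, VWF by 0.66, COL1A1 by 0.73 and COL3A1 by 0.81, but so did other genes of like level, among which they lay at percentiles 34.4 to 84.6. A stronger loss of LMNB1 stays open, since its level was 0.18 above the mean of the other 3 knockdown clones (SD 0.14) as deposited and -0.06 from it (SD 0.14) with each array centred on its median. RNA or hybridisation quality, and a biological difference of this clone, were not tested and stay open.

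The arrays shifted at 1 place along the probe identifiers. Values scaled separately in 2 sets of probes may account for this. The best joint step lay 2 rows from the place where the chromosome 8 identifiers start again, and 0.0238% of rows lie as near. That share counts this 1 place, looked for after the step was seen. Other places where identifiers may start again were not counted, so the share does not measure chance. Chromosome copy number is argued against as the whole cause, since chromosome 8 genes of the 2 interleaved runs differed in 7 of 10 arrays (permutation test of 100000 draws, adjusted over arrays), with p = 1e-05, the smallest it can give, in empty vector clone 2. In that clone the chromosome medians were -0.01 to 0.01 in the first run and -0.11 to -0.07 in the second. No biological explanation was tested beyond copy number.

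Wild type cells and clone 2 shared a difference from the empty vector clones. Sharing of the empty vector arrays is argued against as the whole cause, since with other empty vector clones for each effect the correlation over genes was still at least 0.508 (highest 0.639). An effect of arrays 2 and 3 of clone 2 is argued against as the whole cause, since array 1 alone gave at least 0.345, while as a part of it this stays open, since arrays 2 and 3 minus array 1 correlated with the wild type effect at 0.218. LMNB1 loss is argued against as the whole cause by the design, since wild type cells carry no hairpin. The LMNB1/PCIF1 probe in wild type cells, 1 array, was 0.54 above the empty vector clones (SD 0.17). That level was already known and adds no separate test. A batch of handling and a state common to the empty vector clones stay open and may each give such a pattern.

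Ribosome biogenesis in clone 2 stood at 0.32 (others 0.03 to 0.06). Among the controls, empty vector clone 1 stood apart in LMNA at 9.94 (10.18 to 10.21) and in TAS2R31 at 5.94 (6.60 to 6.71). Wild type cells stood apart in the interferon list at -0.17 (-0.0032 to 0.0050) and the cholesterol list at -0.45 (-0.02 to 0.02).

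Differences between the constructs, clone 2 minus construct V2LHS_62673 with all clones, passed camera for 10 lists and none with an estimated correlation (lowest adjusted p = 0.154). The means were 0.31 for nuclear pore, 0.23 for replication, 0.23 for histones, 0.42 for G2/M and 0.23 for DNA damage. They were -0.20 for leukocyte markers, -0.19 for cholesterol synthesis, 0.30 for ribosomal proteins, 0.27 for ribosome biogenesis and 0.19 for oxidative phosphorylation. Without clone 8, 3 of these lists no longer passed, nuclear pore (0.06), DNA damage (0.0086) and leukocyte markers (-0.03). The other 7 passed, replication at 0.15, histones at 0.24, G2/M at 0.21, cholesterol synthesis at -0.26, ribosomal proteins at 0.26, ribosome biogenesis at 0.27 and oxidative phosphorylation at 0.21. None passed with an estimated correlation without clone 8 either. Oxidative phosphorylation differed among the arrays of clone 2, at -0.17, 0.20 and 0.26 against the empty vector mean, and the difference of 0.19 becomes 0.32 without array 1 and 0.11 without array 3. Array 1 also lay nearest that mean for replication (0.15, 0.34 and 0.45 in arrays 1 to 3) and histones (0.06, 0.35 and 0.41). The same held for ribosomal proteins (0.02, 0.29 and 0.31) and ribosome biogenesis (0.17, 0.32 and 0.45). It did not hold for G2/M (0.27, 0.26 and 0.39) or cholesterol synthesis (-0.47, -0.34 and -0.39).

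The 4 knockdown and 4 control samples can be split in 35 ways. Chance cannot be excluded for the 6 lists in knockdown, where 25 splits gave as many and the highest other gave 15. It cannot be excluded for the 7 chromosomes either, where 15 splits gave as many and the highest other gave 14. For the 5 lists without clone 8, 28 splits gave as many and the highest other gave 16, so chance cannot be excluded. These highest counts are at least 2 times the real ones, but each is the largest picked from all the other splits. No reference was made for how high such a pick would be, so no structure of the samples is inferred from them. In each of these 3 splits wild type cells and clone 2 lie on the same side. For genes the real count was 0, as in all 35 splits, with a highest other of 0. The clones of construct V2LHS_62673 and the empty vector clones can be split in 10 ways, which are too few for a share under 0.05, and the real count and the highest other were both 0.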

How the results depend on the processing

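Centring within identifier runs, the combinations without clone 8 and the fit of arrays of clone 2 alone were chosen after seeing the data, and the other alternatives were planned. The LMNB1 difference kept its direction in all 19 alternatives (-1.55 to -1.33), with an unadjusted limma p of 1.03e-07 to 4.23e-05. In knockdown against controls the gene count of 0 became 6 with array weights, 1 (ZNF738) with each array as a replicate, 2 with the empty vector clones alone, 18 with these and clone 8 left out, and 0 to 2 with single samples left out, the 2 without wild type cells. For construct V2LHS_62673, clone 2, wild type cells and the difference of the constructs, each 0 at first, array weights gave 337, 471, 479 and 371 genes, and leaving out clone 8 gave 110, 418, 400 and 241. All other single omissions gave 0 in these 4. A random block gave 4 (CHI3L1, FSCN1, LRRN1, PLA2G2A), 1 (CFTR) and 4 (CFTR, CHI3L1, FSCN1, PTPRR) for all but wild type cells, and each array as a replicate gave 5, 58 and 15, where the arrays of clone 2 count as clones. No filter gave 1 gene in wild type cells (SH3BGRL). The genes in brackets were named after their values were seen.

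The replicate numbers do not pair the arrays of clone 2 and the empty vector clones, since same-number correlations of the deviations were 0.03, -0.15 and -0.23. With the number as a block 943 genes passed, and 1029 in the same arrays with no block, both with arrays of 1 clone as replicates.

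The 6 lists became 2 with quantile normalization, 10 with no filter, 1 with the 50th percentile filter, 3 with the running median removed, 0 with an estimated correlation, 10 without clone 8 and wild type cells, 0 without clone 8 with an estimated correlation, and 2 (without empty vector clone 2) to 7 with single omissions. The 7 chromosomes became 1 with no filter, 2 with the empty vector clones alone, 0 with an estimated correlation, 0 with identifier runs centred, with or without clone 8, and 2 to 11 with single omissions.

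The mean of nuclear pore genes turned to 0.0022 with array weights, 0.063 without clone 8 and wild type cells, and 0.011 without clone 8 with an estimated correlation, and ranged from -0.27 to 0.01 with single omissions. DNA damage turned to 0.091 with array weights and 0.16 without clone 8 and wild type cells (-0.11 to 0.11 with single omissions), G2/M to 0.17 in the latter (-0.19 to 0.082) and condensin to 0.14. Chromosome means ranged from -0.060 to 0.036 for chromosome 13 and -0.060 to 0.037 for chromosome 18 with single omissions, and without clone 8 and with runs centred they were 0.0080 for chromosome 5, -0.015 for chromosomes 16 and 19 and -0.020 for chromosome 22. Apart from clone 8, whose array enters the spread, the cause was not tested.

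Over 183 named gene results, 4108 of 4272 alternative values kept their side and 164 passed newly, 61 of them without clone 8 and 64 with array weights. None of these genes passed with all clones to begin with. Keeping their side therefore means only that they again did not pass, and does not show that their changes are stable. Over the 27 lists 634 of 727 kept their side, 56 no longer passed, 27 passed newly and 10 reversed, and over the 23 chromosomes the counts were 231 of 299, 49, 13 and 6. A reversal is counted where either value passed. Among those that kept their side, 5 gene, 73 list and 42 chromosome values, none past the threshold, changed sign. Signal over background limits dim probes, which the filter leaves out.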

Other observations

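The list tests outside the main comparison, and the choice to describe wild type cells and clone 2 together, were made after the data were seen. The lists that passed camera in both comparisons with the empty vector clones included DNA replication, histones, G2/M, DNA damage, ribosome biogenesis and heat shock genes on the higher side, and stress response, hypoxia and cholesterol synthesis genes on the lower side. With an estimated correlation over all clones 2 of these lists passed, cholesterol synthesis and ribosome biogenesis (adjusted p = 0.0325 each in clone 2 and adjusted p = 0.019 each in wild type cells), and without clone 8 none did (lowest adjusted p = 0.128 and 0.111). The helicase gene MCM2 was higher than in the empty vector clones by 0.59 in clone 2 and 0.65 in wild type cells. In the same way the mitotic gene BIRC5 was higher by 0.79 in both, and the ribosome assembly gene PES1 by 0.80 and 0.85. SMC3 was higher by 0.79 and 0.76, and also by 0.75 in construct V2LHS_62673 without clone 8. INSIG1, which restrains sterol synthesis, stood at -1.73 and -1.55, and HERPUD1, an endoplasmic reticulum stress gene, at -0.90 and -0.82. Wild type cells had no hairpin and a level of the LMNB1/PCIF1 probe of 9.52, and clone 2 one of 7.67. Part of this pattern was not particular to them. Against the empty vector mean, clones 9 and 12 stood at 0.16 each for DNA damage (clone 2 at 0.17) and -0.17 and -0.12 for hypoxia (-0.18). Replication stood at 0.16 and 0.17 (0.31) and cholesterol synthesis at -0.13 and -0.15 (-0.40). Ribosome biogenesis was nearer the mean, at 0.04 and 0.06 (0.32), and histones in clone 12 went the other way (-0.06).

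Without clone 8, 241 of 11198 genes differed between the constructs, and 13 of them are members of 9 lists that did not pass camera as wholes in this comparison (adjusted p = 0.11 to 0.9). Higher in clone 2 were the goblet cell genes SPINK4 (1.39) and TFF1 (1.35) and the brush border gene VIL1 (0.68) of colon differentiation, JUN (1.04) of immediate early genes, SAMD9 (0.79) and B2M (0.59) of the interferon response, PLAT (0.72) of senescence and RAE1 (0.57) of the nuclear pore. Lower in clone 2 were TGFB2 (-1.73) of the mesenchymal list, EHF (-1.12) of epithelial junctions, PROM1 (-1.01) and BMP4 (-0.70) of the Wnt list and HERPUD1 (-0.86) of the stress response. These genes were named after their values were seen.

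Probes with several gene symbols or none were tested in the main comparison apart from the genes. Of 5184 such probes 0 passed in limma and 199 had an unadjusted p under 0.05.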
